A study of Halobacterium salinarum NRC-1 with 68 samples.

How the data were processed

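RNA of Halobacterium salinarum NRC-1, an archaeon that grows in near-saturated brine, was measured on spotted oligonucleotide arrays with 2 channels. One channel held RNA of an irradiated or control culture and the other held a reference RNA common to the series. Per the labels, the irradiated culture received 2500 Gy of gamma radiation, and the control culture was concentrated in basal salts and returned to medium in the same way. Both were then divided into aliquots that were sampled from 0 to 960 min. The 68 arrays carry 34 RNA samples, 19 irradiated and 15 control, most of them on a pair of arrays with the dyes exchanged. They form 2 labelling sets. The Alexa 532 set has 32 arrays of 16 RNA samples and the Alexa 546 set has 36 arrays of 18 RNA samples, with Alexa 647 as the partner dye in both. Whether the sets come from separate irradiations is not stated in the labels. The series text describes 1 irradiated and 1 control culture split into aliquots, so p-values measure the spread between aliquots and sets, which may be technical.

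The deposited values are log10 ratios per spot, which the authors computed from the raw data together with a statistic named lambda obtained by maximum likelihood, per the labels. The scanner, the background correction and any normalisation within arrays are not given in the sources used here, and channel intensities were not used here, so signal over background is unknown. The deposited ratios cover 10752 spots, which are 2688 features with 4 spots each, with 0 missing values. Array medians lay between 0 and 0.215 on the log10 scale, which shows that the arrays were not all centred on 0. Values of exactly 0 made up to 38.8% of an array's spots, and 9 arrays of 7 RNA samples had over 15%. All 9 were of the Alexa 532 set. They included arrays of that set's only controls at 40 to 60, 120 to 240 and 480 to 960 min. The median over arrays of the SD between the 4 spots of a feature was 0.0796 on the log10 scale. For arrays, the number of arrays and RNA samples limits the precision.

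The labels do not say which channel is the numerator of the deposited ratio, so its direction is not settled. Ratios were turned to culture over reference under 1 reading, channel 1 over channel 2, and every sign below holds for that reading and turns under channel 2 over channel 1. A further reading, culture over reference on every array as deposited, was fitted as an alternative without turning. As deposited, the 2 orientations of an RNA sample correlated at between 0.0042 and 0.805 across spots, which a profile of the dyes or that reading would both give. Arrays of one set and orientation correlated at between 0.0902 and 0.970 across features. Since opposite orientations also correlated positively, this cannot exclude an array whose dyes were exchanged against its label. The scale is stated, while the authors' centring and the direction remain unknown.

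Of the 2688 features, 133 carry 1 gene symbol in the platform annotation, 0 carry several and 2555 are unnamed here. The gene table of the organism belongs to the assembly of another strain, and it was used for gene names and for which genes neighbour each other, with no coordinates. All columns of per-sample values were used; 0 were left out.

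Log10 ratios were multiplied by 3.32 to give log2 ratios, each array was centred on its median, the 4 spots of a feature were averaged, the sign was turned by orientation, and the 2 orientations of an RNA sample were averaged with equal weight, so that a dye pair counted as 1 sample. In the Alexa 546 set, 3 arrays are labelled as control at 50 min and 1 as control at 60 min. One of the 3 may belong to 60 min, but all were kept as labelled. The deviations of the 2 arrays at 50 min that share an orientation correlated at 0.601 across features, against a median of −0.122 and a highest value of 0.623 among the other pairs of 153 in all. The control at 60 min of that set then has a single orientation, and the mean dye profile of its set was subtracted from it.

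Samples were grouped by arm and by 5 time windows. The irradiated and control RNA samples numbered 2 and 2 at 0 min, 6 and 5 at 10 to 30 min, 5 and 4 at 40 to 60 min, 4 and 3 at 120 to 240 min, and 2 and 1 at 480 to 960 min, the last from the Alexa 532 set alone. One linear model per feature in limma 3.58.1 (R 4.3.3; lmFit, contrasts.fit and eBayes) held the 10 groups and the labelling set as an additive term, with 23 residual degrees of freedom and 8.09 prior degrees of freedom. The lone control of the last window is assumed to vary like the other groups. Irradiated was compared with control in each window and as the mean of the first 4 windows. The model also gave the change of that difference between windows, the course of the controls, and the difference between labelling sets. P-values were adjusted by Benjamini-Hochberg over the 2688 features, and a feature was called at an adjusted p under 0.05.

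Genes were named by a rule: in each window, up to 5 called genes with the largest difference on either side and the same sign in both sets, and up to 10 on either side for the mean of 4 windows. Up to 4 members of each described list, and any member of the DNA repair list, could be named too. Other genes or features named were chosen after their values were seen.

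There were 24 gene lists, of which 10 had at least 4 measured genes and were tested: DNA repair, DNA replication, nucleotide synthesis, translation factors and tRNA ligases, chaperones and proteasome, iron and metal genes, chemotaxis, phototrophy, the tricarboxylic acid cycle and amino acid synthesis. A pure culture holds no other cell type. The lists hold 90 of the 133 named genes. Untested lists had 1 or 2 measured genes (ribosomal proteins, oxidative stress, respiratory chain, arginine fermentation, phosphate uptake) or 0 (replication protein A, RNA polymerase, transcription factors, gas vesicles, archaella, ATP synthase, cell division, insertion sequences, replicon genes). Each list was tested in 6 comparisons with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, and p-values were adjusted over the 60 tests. The camera test compares a list with the rest of the 133 named genes, most of which belong to other lists, and not with all features. In fry, 1 p-value tests whether a list's genes move, on balance, one way and the mixed p-value tests whether they change in either direction; neither compares the list with other genes.

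The grouping, the model, the rule for named genes, the lists and most alternatives were chosen before the data were examined. The alternatives covered array scaling, the summary of spots, filters on features, the labelling set, single orientations, arrays as units, matched times, moderated variance with a trend, a minimum fold of 1.5, and leaving out each RNA sample in turn. A planned filter for features with a value on every array removed nothing and was run as a filter for features with a value other than 0 on every array. After the data were seen, 5 alternatives were added: ratios not turned between orientations, the lone sample without dye correction, removal of each array's smooth trend by loess (span 0.4), exact 0 taken as missing, and leaving out the 7 RNA samples with over 15% exact 0. The smooth trend was that of an array's deviation from the mean ratio of its set and orientation, fitted against that mean ratio.

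The model was tested on simulated data for 2688 features with the spread of these samples. At 10 to 30 min it called 72% of features shifted by 0.3 and 98% of those shifted by 0.6 on the log2 scale. These shares were 56% and 97% at 40 to 60 min, 43% and 95% at 120 to 240 min, 9% and 73% at 0 min, 8% and 55% at 480 to 960 min, and 97% and 99% for the mean of 4 windows. For the change from 0 min to 10 to 30 min they were 10% and 74%, for the change from there to 120 to 240 min 17% and 82%, for the control course 21% and 91%, and for the difference between sets 35% and 97%. In the simulation at 10 to 30 min all 10 lists shifted by 0.3 were called by camera, and 0 of 90 tests of unshifted lists. The simulated noise was independent between features, and p-values were adjusted over 10 lists and not over 60 tests. In the real samples the estimated correlation within a list reached 0.386, for the tricarboxylic acid cycle. The 0 calls of unshifted lists therefore do not show how often camera calls unshifted lists of correlated genes. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.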

Results

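Halobacterium salinarum NRC-1 was followed for up to 960 min after 2500 Gy of gamma radiation beside a control culture, to describe the response of its transcripts to the radiation. The 68 arrays held 34 RNA samples, 19 of irradiated and 15 of control aliquots, each read against the same reference RNA. Irradiated and control RNA samples numbered 2 and 2 at 0 min, 6 and 5 at 10 to 30 min, 5 and 4 at 40 to 60 min, 4 and 3 at 120 to 240 min, and 2 and 1 at 480 to 960 min, in labelling sets with Alexa 532 (16 samples) or Alexa 546 (18 samples). Of 2688 features, 133 are named genes, and counts of features below refer to all 2688. Values are log2 ratios to the reference, and a difference is irradiated minus control. Signs hold for the deposited ratio read as channel 1 over channel 2. Read as channel 2 over channel 1 every sign turns, while sizes, and which genes stood on opposite sides, stay as given. Positive and negative therefore name the sides of a difference and not induction or repression. Under a further reading, in which each array was deposited as culture over reference and is not turned, sizes and sides change too, so the values below depend on a ratio between fixed channels, which the labels do not settle.

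At 10 to 30 min the genes of DNA gyrase, gyrA and gyrB, stood on the positive side together with dpsA, which encodes a ferritin-like protein that stores iron. The difference of dpsA was 0.50 ± 0.11 (SE) or 1.42-fold, with ratios of 0.25 ± 0.25 (SD, n = 6) in irradiated and −0.28 ± 0.39 (SD, n = 5) in control RNA samples (limma adjusted p = 0.00789). In single labelling sets it was 0.15 (Alexa 532) and 0.78 (Alexa 546). gyrA differed by 0.34 ± 0.07 (1.26-fold, adjusted p = 0.00289) and gyrB by 0.33 ± 0.06 (1.25-fold, adjusted p = 0.00197). On the same side stood guaB, the gene of IMP dehydrogenase in guanine nucleotide synthesis, at 0.35 ± 0.09 (adjusted p = 0.0257), and psmA, a proteasome subunit gene, at 0.28 ± 0.08 (adjusted p = 0.0364). Set against the controls of its own labelling set, each of gyrA, gyrB and guaB was on this side in 6 of 6 irradiated RNA samples. dpsA and psmA were in 5 of 6. Such counts, here and below, come from the samples that chose the genes, so they describe the calls and are no separate support. In some windows a set has 1 control, with which all its irradiated samples were compared. When RNA samples were left out in turn, the calls of dpsA, gyrA and gyrB were made in 34 of 34 fits, that of guaB in 28 (0.29 to 0.40) and that of psmA in 27 (0.24 to 0.33).

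On the negative side at 10 to 30 min pyrI, a subunit gene of aspartate carbamoyltransferase in pyrimidine synthesis, differed by −0.38 ± 0.10 (1.30-fold, adjusted p = 0.0201), and mdh, the malate dehydrogenase gene, by −0.37 ± 0.10 (1.29-fold, adjusted p = 0.0225). glyA, the gene of serine hydroxymethyltransferase, differed by −0.35 ± 0.10 (adjusted p = 0.0383). The cobalamin genes cbiT and cobN differed by −0.35 ± 0.08 (adjusted p = 0.00732) and −0.32 ± 0.07 (adjusted p = 0.0112). All 5 genes were on this side in 6 of 6 irradiated RNA samples. With RNA samples left out in turn, cbiT and cobN were called in 34 of 34 fits, pyrI in 31, mdh in 30 and glyA in 28. Of 13 named genes called, 5 were positive and 8 negative, the others being sucD (−0.29 ± 0.08), purL (−0.24 ± 0.07) and serS (−0.24 ± 0.07).

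Over all features, 121 were called at 10 to 30 min, 71 positive and 50 negative, and 429 had an unadjusted p under 0.05 where 134.4 were expected by chance. The labelling sets called 8 (Alexa 532) and 70 (Alexa 546) features alone, and across features, which are not independent replicates, the differences of the 2 sets correlated at 0.35. The count was 77 with arrays scaled to a common spread, 80 with quantile normalisation, 31 without the set term in the model, 23 with the single 60 min control array left uncorrected for the dye, and 10 for a difference of at least 1.5-fold. It was 62 without the control of 10 min in the Alexa 546 set and 73 without that of the Alexa 532 set. It was 282 from arrays with the culture RNA in Alexa 647 and 1 from arrays with it in Alexa 532 or 546 (limma; 368 at an unadjusted p under 0.05). With ratios not turned 148 features were called at 10 to 30 min, 32 positive and 116 negative, and 0 of them were among the 121 on the same side. dpsA was then at −0.10 ± 0.08 (adjusted p = 0.47), gyrA at −0.31 ± 0.10 (adjusted p = 0.0615) and gyrB at −0.29 ± 0.09 (adjusted p = 0.0543), and the named genes called were gdhA2 (0.63 ± 0.11), purD (0.50 ± 0.11) and secF (0.30 ± 0.09).

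**Figure D1:**
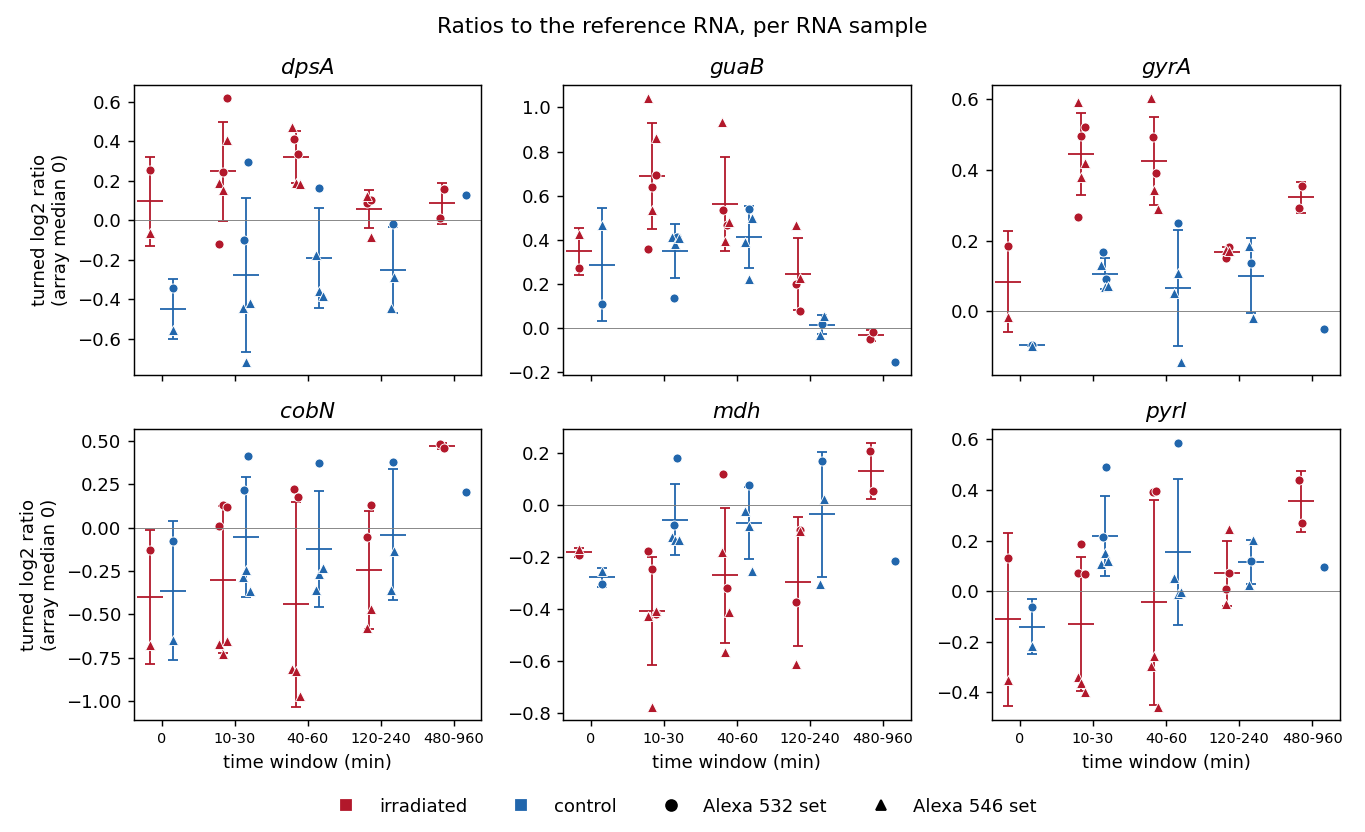
Turned log2 ratios of 6 genes (y axis, array median 0) in each RNA sample by time window in minutes (x axis), irradiated in red and control in blue, with circles for the Alexa 532 set, triangles for the Alexa 546 set, and bars for the mean ± SD over both sets where a group has more than 1 sample. At 10 to 30 min the mean of gyrA was 0.45 in irradiated and 0.11 in control samples, and that of mdh was −0.41 and −0.06.

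The genes were also read by dye orientation, because the call counts of the 2 orientations differed. At 10 to 30 min gyrA differed by 0.65 ± 0.12 with the culture RNA in Alexa 647 and by 0.02 ± 0.11 with it in Alexa 532 or 546, and gyrB by 0.62 ± 0.11 and 0.03 ± 0.10. For both genes the difference itself changed with orientation (limma adjusted p = 0.0371 and 0.0375). purD, a purine synthesis gene, was on opposite sides at −0.69 ± 0.15 and 0.31 ± 0.11 (adjusted p = 0.0249 for the change). htr8 (0.39 and −0.06) was on opposite sides too, and sucC (−0.42 and −0.002), purL (−0.41 and −0.07) and uvrB (0.38 and 0.06) were near 0 in Alexa 532 or 546. A change was not called for htr8, sucC, purL or uvrB (limma adjusted p between 0.101 for htr8 and 0.293 for sucC). The values of dpsA were 0.60 ± 0.12 and 0.40 ± 0.15, those of guaB 0.29 ± 0.11 and 0.42 ± 0.14, those of pyrI −0.45 ± 0.14 and −0.31 ± 0.13, and those of cbiT −0.30 ± 0.12 and −0.40 ± 0.12. For these 4 genes a change with orientation was not called at 10 to 30 min (adjusted p between 0.438 for dpsA and 0.794 for cbiT). In all, 156 features changed with orientation at 10 to 30 min, 20 of them among the 121 called over both orientations. Across all features the differences of the 2 orientations correlated at −0.21. The 282 features called with the culture RNA in Alexa 647 had a median of −0.04 along their called side in the other orientation.

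**Figure D2:**
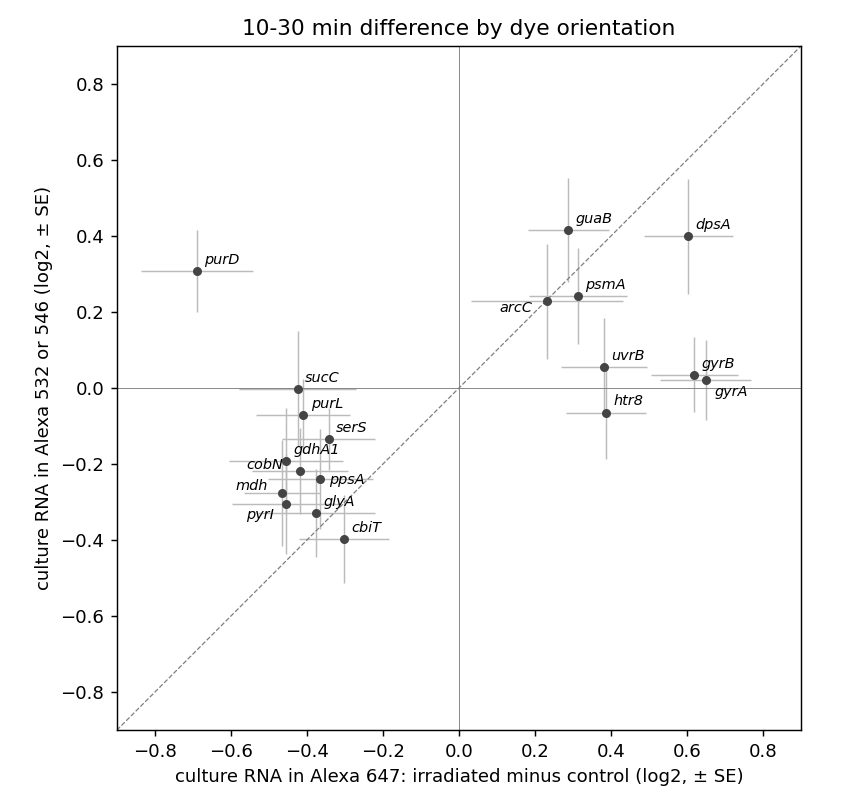
Irradiated minus control at 10 to 30 min (log2, ± SE) for 19 named genes, with the culture RNA in Alexa 647 on the x axis and in Alexa 532 or 546 on the y axis, and the dashed line marking equal values. gyrA (0.65 and 0.02) and gyrB (0.62 and 0.03) lie near 0 on the y axis, purD (−0.69 and 0.31) lies on opposite sides, and dpsA (0.60 and 0.40) lies on one side.

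At 40 to 60 min dpsA, gyrA and gyrB were again on the positive side and cobN on the negative. dpsA differed by 0.47 ± 0.13 (1.39-fold, limma adjusted p = 0.0461), gyrA by 0.35 ± 0.07 (1.28-fold, adjusted p = 0.00899) and gyrB by 0.26 ± 0.07 (1.20-fold, adjusted p = 0.0461). cobN differed by −0.43 ± 0.08 (1.34-fold, adjusted p = 0.00402), and ppsA, the gene of phosphoenolpyruvate synthase, by −0.47 ± 0.13 (1.39-fold, adjusted p = 0.0461). The ratios of ppsA were −0.64 ± 0.36 (SD, n = 5) in irradiated and −0.22 ± 0.14 (SD, n = 4) in control samples. All 5 genes held their side in 5 of 5 irradiated RNA samples, but 3 of the calls ended in many fits with 1 RNA sample left out. Of 34 such fits dpsA was called in 17 (0.41 to 0.54 over all 34), gyrB in 15 (0.22 to 0.31) and ppsA in 13 (−0.55 to −0.39), against 34 for cobN and 33 for gyrA, whose call ended without the irradiated sample of 40 min of the Alexa 546 set. In single labelling sets (Alexa 532 and 546) dpsA was at 0.21 and 0.59, ppsA at −0.27 and −0.60, and cobN at −0.17 and −0.58. With the culture RNA in Alexa 532 or 546 alone, gyrB was at −0.05.

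In this window 47 features were called, 41 positive and 6 negative, and 327 had an unadjusted p under 0.05. Across features the differences of the 2 sets correlated at 0.12, and the Alexa 532 set called 0 features alone (limma; 201 at an unadjusted p under 0.05) and the Alexa 546 set 39. The count was 15 without the irradiated sample of 40 min, 23 without the control of 40 min and 29 without the control of 50 min, all of the Alexa 546 set. With arrays scaled to a common spread it was 0 (limma; 204 at an unadjusted p under 0.05), with quantile normalisation it was 2, and without the set term 12. With ratios not turned 29 were called, 14 positive and 15 negative, with 0 of the 47 among them on the same side.

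Over the mean of the first 4 windows, dpsA led the positive side at 0.45 ± 0.07 (1.36-fold, limma adjusted p = 0.000156), on that side in 16 of 17 irradiated RNA samples. It was followed by arcC, the carbamate kinase gene of arginine fermentation, at 0.30 ± 0.09 (1.23-fold, adjusted p = 0.0319), and by gyrA at 0.23 ± 0.04 and gyrB at 0.22 ± 0.04 (both adjusted p = 0.000767). guaB was at 0.21 ± 0.06 (adjusted p = 0.0294). uvrB, a gene of nucleotide excision repair, was at 0.20 ± 0.05 (adjusted p = 0.0166), on that side in 14 of 17 samples. The transducer gene htr8 was at 0.18 ± 0.05 (adjusted p = 0.0262). With RNA samples left out in turn, dpsA, gyrA and gyrB were called in 34 of 34 fits, uvrB in 32, htr8 in 31, guaB in 29 and arcC in 27.

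The negative side over the 4 windows was led by sucC, a succinyl-CoA synthetase gene, at −0.32 ± 0.06 (1.25-fold, adjusted p = 0.00156), and by cobN at −0.28 ± 0.05 (1.21-fold, adjusted p = 0.000348). cobN and purL, another purine synthesis gene (−0.22 ± 0.04, adjusted p = 0.00245), were on that side in 17 of 17 irradiated samples. glyA (−0.26), gdhA1, a glutamate dehydrogenase gene (−0.24), cbiT (−0.20), mdh (−0.20), purD (−0.16) and serS, the gene of seryl-tRNA synthetase (−0.15), were called too, with adjusted p between 0.0116 for cbiT and 0.0446 for mdh. With RNA samples left out in turn, mdh was called in 16 of 34 fits (−0.23 to −0.17), gdhA1 in 28, serS in 30, cbiT and purD in 33, and sucC, cobN, purL and glyA in 34. In the mean of 4 windows the difference of gyrA, gyrB, guaB and uvrB changed with dye orientation (adjusted p = 0.0332, 0.0125, 0.0230 and 0.0376). Over all features 110 changed with orientation there, 46 of them among the 209 called over both orientations. Under Alexa 532 or 546 alone purD (0.05) and serS (0.01) turned to the positive side.

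In all, 209 features were called over the 4 windows, 136 positive and 73 negative. The count was 38 with arrays scaled to a common spread and 60 with quantile normalisation. It was 84 without the set term and 98 with the single 60 min control array uncorrected. For a difference of at least 1.5-fold it was 0 (limma, where 561 features of any fold had an unadjusted p under 0.05). Across features the differences of the 2 sets correlated at 0.24. The Alexa 532 set alone called 175, of which 39 were positive and 136 negative and 42 were among the 209. The Alexa 546 set alone called 62, of which 33 were positive and 29 negative and 53 were among the 209. With ratios not turned 86 were called, 7 positive and 79 negative, with 0 of the 209 among them on the same side. dpsA was then at −0.13 ± 0.05 (adjusted p = 0.171) and cobN at 0.05 ± 0.06, and gyrB (−0.21 ± 0.06) and guaB (−0.20 ± 0.05) were called on the other side. From single dye orientations the counts were 340 with the culture RNA in Alexa 647 and 0 in Alexa 532 or 546 (limma; 228 at an unadjusted p under 0.05). Of the fits with an RNA sample left out, the count was 121 without the control of 0 min or without the irradiated sample of 0 min of the Alexa 532 set, and 356 without the control of 0 min of the Alexa 546 set. Of the unnamed features, 2471 (0.58 ± 0.07, adjusted p = 6.02e-06) and 4099 (0.58 ± 0.12) had the largest positive differences, and 1223 (−0.46 ± 0.10) and 3453 (−0.43 ± 0.09) the largest negative ones. When ratios were not turned, 2471 (−0.32 ± 0.06, adjusted p = 0.00132) and 4099 (−0.23 ± 0.07, adjusted p = 0.0674) were on the other side, and 1223 (−0.02 ± 0.05) and 3453 (−0.05 ± 0.08) were near 0.

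At 0 min no named gene was called. The difference of dpsA was 0.54 ± 0.19 (adjusted p = 0.431), with ratios of 0.10 ± 0.23 (SD, n = 2) in irradiated and −0.45 ± 0.15 (SD, n = 2) in control samples, and that of sucC was −0.48 ± 0.16 (adjusted p = 0.431). uvrB was at 0.33 ± 0.14 (adjusted p = 0.555). Of the 121 features called at 10 to 30 min, 90 were on the same side at 0 min. The 3 called features were unnamed, 2841 (0.80 ± 0.15) and 3353 (0.73 ± 0.15) on the positive side and 1797 (−0.72 ± 0.15) on the negative, and 235 features had an unadjusted p under 0.05. Between the sets the differences correlated at −0.22 across features, and the Alexa 532 set, with 1 sample in each arm, called 201 features alone, 5 positive and 196 negative with 2 of the 3 among them, and the Alexa 546 set 0 (limma; 152 at an unadjusted p under 0.05). The count was 91 without the control of the Alexa 546 set. With arrays scaled to a common spread it was 0 (limma; 134 at an unadjusted p under 0.05). It was also 0 with ratios not turned (limma; 154), and 2841 and 3353 were at −0.47 ± 0.12 and −0.41 ± 0.12.

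At 120 to 240 min no named gene was called either. dpsA was at 0.27 ± 0.14 (adjusted p = 0.591), with ratios of 0.06 ± 0.10 (SD, n = 4) in irradiated and −0.25 ± 0.22 (SD, n = 3) in control samples. gyrA was at 0.06 ± 0.08 (adjusted p = 0.820) and gyrB at 0.10 ± 0.08 (adjusted p = 0.699), and both turned negative when arrays were scaled to a common spread or quantile normalised. sucC was at −0.41 ± 0.12 and cobN at −0.32 ± 0.09 (both adjusted p = 0.274). The 1 feature called was the unnamed feature 3453 at −1.01 ± 0.17 (adjusted p = 0.00386), and 240 had an unadjusted p under 0.05. Without the control of 240 min of the Alexa 546 set 0 were called (limma). Ratios not turned gave 15 calls, all negative, and 3453 was at −0.15 ± 0.15 (adjusted p = 0.555).

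At 480 to 960 min, with 2 irradiated samples against 1 control, no named gene was called. The gyrase genes were at 0.39 ± 0.13 for gyrB (adjusted p = 0.138) and 0.37 ± 0.13 for gyrA (adjusted p = 0.189), and dpsA was at −0.04 ± 0.23 (adjusted p = 0.939). rpl12p, a ribosomal protein gene and the single measured member of its list, was at 0.78 ± 0.23 (adjusted p = 0.123) and was chosen after its value was seen. Of the 121 features called at 10 to 30 min, 47 were on the same side in this window. The control is among the 7 RNA samples with over 15% exact 0, at 24.6% on 1 of its arrays. Leaving out those samples leaves no control in this window. The 3 called features were unnamed, 11 (0.65 ± 0.12) and 103 (0.62 ± 0.12) on the positive side and 5177 (−0.99 ± 0.21) on the negative, and 382 had an unadjusted p under 0.05. The count was 174 with arrays scaled to a common spread and 38 without the irradiated sample of 480 min, and without centring the median of all features moved by −0.13 and 3 features were called, 0 positive and 3 negative with 1 of the former 3 among them (limma). Ratios not turned gave 2 calls, both negative, and 11 and 103 were at −0.27 ± 0.16 and −0.36 ± 0.14.

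The change of the response between windows was tested directly. From 0 min to 10 to 30 min the differences of dpsA (0.54 and 0.50) and gyrA (0.18 and 0.34) did not change detectably, and limma called 0 features, with 183 at an unadjusted p under 0.05. From 10 to 30 min to 120 to 240 min the difference of gyrA went from 0.34 to 0.06 and that of dpsA from 0.50 to 0.27, and again limma called 0 features, with 147 at an unadjusted p under 0.05. Of the 121 features called at 10 to 30 min, 115 were on the same side at 40 to 60 min and 100 at 120 to 240 min. The windows share no samples, but the series text describes 1 irradiated and 1 control culture. Agreement of side between windows is therefore not replication by separate cultures. Without the control of 0 min of the Alexa 546 set the first change had 20 calls, and from Alexa 647 arrays alone the second had 323 and with ratios not turned 359.

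The control cultures were also concentrated and returned to medium, so their own course was followed from 0 min to 120 to 240 min. hisA, a histidine synthesis gene, changed by −0.43 ± 0.09 (adjusted p = 0.0359). It was the 1 named gene among 3 features called, the others being unnamed features 3453 (1.46 ± 0.20, adjusted p = 0.000122) and 3717 (−1.25 ± 0.26, adjusted p = 0.0359). Feature 3453 is also the one called between the arms at 120 to 240 min, and both comparisons use the same 3 control samples. In all 268 features had an unadjusted p under 0.05. The call of hisA ended with arrays scaled to a common spread (−0.39 ± 0.11, adjusted p = 0.367), with quantile normalisation (−0.45 ± 0.12, adjusted p = 0.186) and without the set term (−0.42 ± 0.09, adjusted p = 0.211). The feature counts under these 3 settings were 0 (limma; 199 at an unadjusted p under 0.05), 1 and 0 (limma; 127). The call also ended in each labelling set alone (adjusted p = 0.552 and 0.183), with the single 60 min control array uncorrected (adjusted p = 0.291) and without the samples rich in exact 0 (adjusted p = 0.0775). With the culture RNA in Alexa 647 alone hisA was at −0.77 ± 0.16 (adjusted p = 0.0241), and in Alexa 532 or 546 alone at −0.09 ± 0.13 (adjusted p = 0.773). Not turned, hisA was at 0.34 ± 0.12 (adjusted p = 0.230), 3453 was at 0.09 ± 0.18, 3717 was at 0.92 ± 0.21, and 0 features were called (limma; 337). Between 1 and 11 features were called when RNA samples were left out in turn, with 11 without the irradiated sample of 480 or that of 960 min and 1 without the control of 20, 120 or 240 min of the Alexa 546 set.

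Whether the response differed between the labelling sets was tested over the 4 shared windows. The differences of dpsA were 0.27 in the Alexa 532 and 0.56 in the Alexa 546 set, those of gyrA 0.20 and 0.24, and those of cobN −0.20 and −0.32. limma called 0 features for the difference between sets, with 268 at an unadjusted p under 0.05. From arrays with the culture RNA in Alexa 647 alone it called 253, with ratios not turned 75, and without the control of 50 min of the Alexa 546 set 9. It called 59 without the 7 RNA samples with over 15% exact 0, all of the Alexa 532 set.

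Over the mean of 4 windows 3 of 4 genes of DNA repair and 3 of 4 of DNA replication were positive. In the repair list, uvrB was called over the mean of 4 windows, 1 of 4 members, and 2 of 4 passed when adjusted over the list alone, the second being uvrA (0.12 ± 0.05, adjusted p over all features 0.133). radB was at 0.08 ± 0.04 and mutL at −0.05 ± 0.06. The list median was 0.10 (camera adjusted p = 0.163, fry adjusted p = 0.00896). In the replication list, gyrA and gyrB were called at 10 to 30 min, 40 to 60 min and over the mean of 4 windows, 2 of 4 members and also 2 adjusted over the list alone, while orc7 (0.08 ± 0.06) and orc8 (−0.01 ± 0.08), which encode origin recognition proteins, were not. The list's median over the 4 windows was 0.15 (camera adjusted p = 0.0570, fry adjusted p = 0.00896). These sides reversed with ratios not turned: over the mean 3 of 4 repair genes were negative with a median of −0.10 (camera adjusted p = 0.357, fry adjusted p = 0.0541), and so were all 4 replication genes with a median of −0.10 (camera adjusted p = 0.363, fry adjusted p = 0.147).

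Of 5 genes of the tricarboxylic acid cycle, 4 were negative at 10 to 30 min and all 5 at 40 to 60 and at 120 to 240 min. mdh and sucD were called at 10 to 30 min, 2 of 5 members and also 2 adjusted over the list alone, with a list median of −0.21 (camera adjusted p = 0.0917). Over the mean of 4 windows 2 members were called, mdh and sucC, and 3 adjusted over the list alone, with sucD (−0.15 ± 0.05). citZ was at −0.10 ± 0.05 and icd at 0.00 ± 0.05. At 120 to 240 min the median was −0.15, and camera called the list (adjusted p = 0.0337; adjusted p = 0.310 with an estimated correlation), with 0 members called over all features (limma) and 1, sucC, adjusted over the list alone. In single labelling sets camera did not call the list, with an adjusted p of 0.0805 in the Alexa 546 set. At 480 to 960 min all 5 were positive with a median of 0.29 (camera adjusted p = 0.131), though sucC turned negative without centring and under both scalings. In ratios not turned 4 of 5 were positive at 10 to 30 min, at 40 to 60 min and over the mean, where the median was 0.07 (camera adjusted p = 0.325), 2 of 5 were positive at 120 to 240 min with a median of −0.02, and all 5 were negative at 480 to 960 min.

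The list of iron and metal genes measured here held cbiG, cbiT and cbiQ, which belong to cobalamin synthesis and cobalt uptake, and hutG, hutI and hutU, which belong to histidine breakdown. At 120 to 240 min all 6 were negative with a median of −0.19, and camera called the list (adjusted p = 0.0120; adjusted p = 0.149 with an estimated correlation). No member (0) was called over all features in limma, and 3, cbiT (−0.24 ± 0.10), cbiQ (−0.23 ± 0.09) and hutG (−0.18 ± 0.07), passed adjusted over the list alone. With arrays scaled to a common spread or quantile normalised, 3 of the 6 turned positive and the median was −0.06 and −0.02. In single labelling sets camera did not call it in the Alexa 532 set (adjusted p = 0.0725) and did in the Alexa 546 set (adjusted p = 0.0103; adjusted p = 0.457 with an estimated correlation). At 120 to 240 min 4 of 6 were negative with ratios not turned, with a median of −0.04, and relative to the other named genes camera put the list on the positive side (adjusted p = 0.595).

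Among 16 genes of nucleotide synthesis, guaB was called on the positive side and purL and pyrI on the negative at 10 to 30 min, and 5 members passed adjusted over the list alone, with pyrB (−0.24 ± 0.08) and purD (−0.19 ± 0.06). Over the mean of 4 windows 13 of 16 were negative with a median of −0.07, 3 were called and 5 passed adjusted over the list alone (camera adjusted p = 0.131, fry adjusted p = 0.00896). At 480 to 960 min 14 of 16 were positive (camera adjusted p = 0.535), and 8 of 16 without centring. Over the mean 10 of 16 were positive with ratios not turned, with a median of 0.02 (camera adjusted p = 0.325, fry adjusted p = 0.635), and 7 of 16 at 480 to 960 min. Among 14 genes of amino acid synthesis glyA was called over the mean of 4 windows, 1 also adjusted over the list alone (camera adjusted p = 0.535), with hisF (−0.17 ± 0.06) passing the latter at 10 to 30 min. Of 12 genes of the tRNA ligase list serS was called, 1 also adjusted over the list alone, while the list's median over 4 windows was 0.04 and turned negative under both scalings (camera adjusted p = 0.719). Over the mean, 11 of 14 genes of amino acid synthesis were negative with ratios not turned (camera adjusted p = 0.572), and 6 of 12 of the tRNA ligase list (camera adjusted p = 0.543).

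Of 6 genes in the chaperone and proteasome list, psmA was called at 10 to 30 min, 1 also adjusted over the list alone. At 40 to 60 min 0 were called over all features (limma), while dnaJ (0.32 ± 0.10), psmA (0.23 ± 0.09) and psmB (0.17 ± 0.07) passed adjusted over the list alone, 3 of 6 (camera adjusted p = 0.0917). This list also took in panB, a symbol used for a gene of pantothenate synthesis and for a proteasome ATPase gene, at −0.09 ± 0.09. Of 11 chemotaxis genes htr8 was called over the mean of 4 windows and 2, htr8 and htr7 (0.12 ± 0.04), passed adjusted over the list alone (camera adjusted p = 0.842). Of the 4 phototrophy genes hop, bat, sop1 and sop2, 0 were called in any window (limma), with means of 4 windows between −0.03 and 0.08 (camera adjusted p = 0.719). In ratios not turned 5 of 6 genes of the chaperone and proteasome list were negative at 40 to 60 min (camera adjusted p = 0.367), and over the mean 10 of 11 chemotaxis genes (camera adjusted p = 0.343) and all 4 phototrophy genes (camera adjusted p = 0.367). Among lists too small to test, dpsA was called beside msrA at 0.05 ± 0.05, and arcC beside arcA at 0.18 ± 0.08.

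Over the 60 list tests camera with the preset correlation called 2, the tricarboxylic acid cycle and the iron and metal genes at 120 to 240 min, and with an estimated correlation or with ratios not turned it called 0. Tests for movement on balance one way passed in 17 with fry, and 0 passed its mixed test. The median, mean and camera direction of a list differed in sign in 11 of the 60 tests, none of them called by camera.

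**Figure D3:**
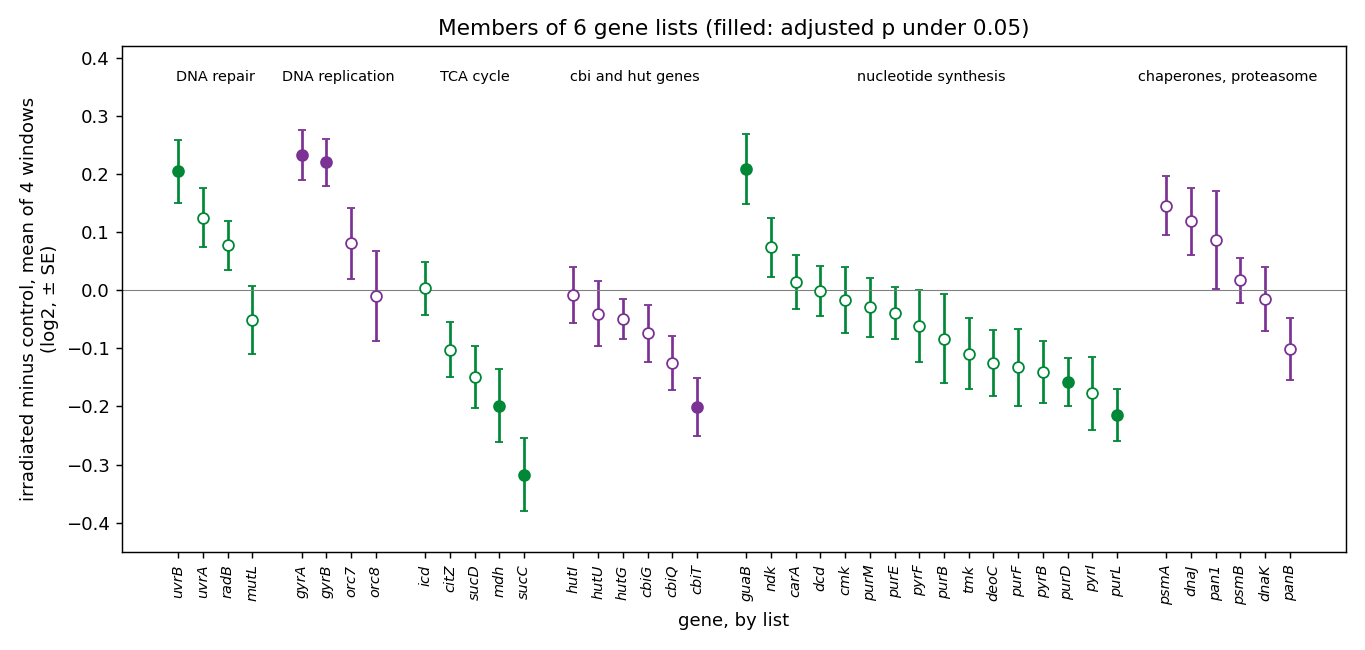
Irradiated minus control as the mean of 4 windows (y axis, log2 ± SE) for the members of 6 gene lists (x axis, genes by list), with filled points for adjusted p under 0.05 over all features. gyrA (0.23) and gyrB (0.22) stand above orc7 (0.08) and orc8 (−0.01), and sucC (−0.32) and mdh (−0.20) lie on the negative side of the tricarboxylic acid cycle list.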

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

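The tests of orientation by level of the ratio, and those of the direction of the ratio, were chosen after the results were seen. The other tests in this part were planned before their results were seen.

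In 6 of 86 groups of 4 to 6 RNA samples, 1 sample stood farther from the others than Dixon's limit, where 1 in 20 groups, or 4.3, would pass by chance if a group held no structure. The groups pool both labelling sets, so a difference between sets can also pass. In the controls of 10 to 30 min, guaB was 0.14 in the 10 min sample of the Alexa 532 set against 0.38 to 0.41 in the others. The 30 min control of that set had pyrI at 0.49 against 0.11 to 0.21 and mdh at 0.18 against −0.13 to −0.076. It had 38.8% exact 0 on 1 array. Without it the calls of mdh and glyA at 10 to 30 min were lost, and that of pyrI was kept. The 60 min control of that set, the only sample of the set in its group, had cobN at 0.37 against −0.36 to −0.24. It had 19.1% exact 0 on 1 array. The irradiated sample of 240 min in the Alexa 546 set had dpsA at −0.085 against 0.090 to 0.13 in its window. The irradiated sample of 40 min in that set had guaB at 0.93 against 0.39 to 0.54.

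Other splits of the same RNA samples, with the real one counted, were set beside the call counts. At 10 to 30 min 1 of 100 splits gave as many calls as the real 121, the highest other giving 52. Over the mean of 4 windows 1 of 100 gave as many as 209, the highest other giving 34. A chance assignment of aliquots to the arms is therefore argued against for both. The splits cannot exclude a chance difference between the cultures, since the series text describes 1 irradiated and 1 control culture. Splits of the arms were also drawn without regard to labelling set. At 40 to 60 min 2 of 100 splits gave as many as 47. By share this argues against a chance assignment of aliquots, although 1 other split called 101. What set that split apart was not tested. At 120 to 240 min 4 of 35 splits gave as many as the real 1, the highest other giving 4, so chance cannot be excluded. For the change from 10 to 30 min to 120 to 240 min and for the difference between labelling sets the real count was 0 (limma; 147 and 268 at an unadjusted p under 0.05), so 100 of 100 splits reach it by construction and the splits decide nothing. The highest other splits gave 2 and 182. A split with 182 calls points to some structure of the samples, which was not tested. For the gene lists 13 of 100 splits gave as many calls as the real 2, the highest other giving 4, so chance cannot be excluded for the calls of the tricarboxylic acid cycle and the iron and metal genes.

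At 10 to 30 min 282 features were called with the culture RNA in Alexa 647 and 1 with it in Alexa 532 or 546. A smooth trend of the arrays along the mean ratio of their set and orientation is argued against. After its removal from each array 253 features were called in the Alexa 647 orientation. Of these 188 were among the 282 and on the same side. Trends with signal intensity or with position on the array were not tested for this pattern. Ratios compressed toward 0 in the other orientation would keep the side of a difference: that side was kept by 63.6% of the 165 called features whose mean ratio lay below the median of all features, where gyrA, gyrB and dpsA lie, but by 17.9% of the 117 above it, so compression is argued against for the latter. Above the median, a shift of the deposited ratio that follows the arm in both orientations is a candidate explanation. With ratios between fixed channels such a shift is no change of transcripts and cancels in the average of both orientations, while with ratios deposited as culture over reference it would be the change of transcripts, and this was not settled. The design gives no biological difference between orientations, which carry the same RNA.

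The counts went from 121 called features at 10 to 30 min to 1 at 120 to 240 min, with gyrA at 0.34 and 0.06. Fewer samples alone are argued against, since 10 to 30 min thinned to 4 irradiated and 3 control samples gave a median of 23 calls over 100 draws, from 3 to 89, and 0 draws at or below the count of 1. Over the 47 features called at 40 to 60 min, the mean difference along the called side was 0.31 ± 0.06 (SE) at 10 to 30 min and 0.20 ± 0.05 at 120 to 240 min (exact permutation p = 0.185, two-sided, 3000 permutations). Whether the difference between the arms itself shrank with time after irradiation, the biological explanation the design offers, is therefore open.

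Which channel is the numerator of the deposited ratio decides whether dpsA and gyrA are higher or lower after irradiation. Differences between arms had an SD over features 2.19 times larger with the culture RNA in channel 2 in the Alexa 532 set and 1.70 times larger in the Alexa 546 set. The surface glycoprotein gene csg and the ribosomal gene rpl12p lay at the 0.446th and 6.14th percentile of the mean deposited ratio over all arrays, each centred on its median. Both values could arise under either order of the channels, since channel intensities were not used here, and the 2 orders cannot be told apart. The other question is whether each array was deposited as culture over reference, in which case the deviations of an RNA sample from the mean of its set and orientation would go the same way in both orientations as deposited, or between fixed channels, in which case they would go opposite ways. Over 33 flip pairs their median correlation was 0.107 across all features, with 23 positive and 10 negative (sign test p = 0.0351). In 4 equal parts of the features by mean ratio, from the lowest up, it was −0.087, 0.074, 0.169 and 0.268, with 22, 11, 7 and 6 of the 33 negative. The sign test p was 0.0801, 0.0801, 0.00132 and 0.000324. Only the 2 upper parts passed at 0.05, and both went the way of culture over reference. No part passed for fixed channels, though the lowest leaned that way. Neither reading passed in all 4 parts, so this test does not tell the 2 readings apart. The sizes and sides given in the report depend on a ratio between fixed channels. No biological explanation was tested for this pattern.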

How the results depend on the processing

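The alternatives added after the data were seen were ratios not turned between orientations, the single 60 min control array without dye correction, removal of smooth trends, exact 0 as missing, and leaving out samples rich in exact 0. The other alternatives were planned, except that the difference between sets was planned for the scaling as deposited and for left-out samples alone. Counts are features called by limma, unless said otherwise, and the cause of a change was not tested in this part. A stricter threshold can only lower a count.

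Of 206 counts under other settings 111 were within 1.5 times the main count, 51 were lower and 44 higher. Of 651 values of named genes 399 kept their side and call, 222 kept the side without the call and 30 reversed, 27 of them with ratios not turned. With the culture RNA in Alexa 532 or 546 alone gyrB at 40 to 60 min was −0.053, and purD and serS over the mean of 4 windows were 0.047 and 0.0088. Moderated variance with a trend and leaving out the third control array of 50 min kept each count they were run for within 1.5 times, moderated variance not being run for the difference between sets.

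The main counts were 3 at 0 min, 121 at 10 to 30 min, 47 at 40 to 60 min, 1 at 120 to 240 min, 3 at 480 to 960 min, 209 for the mean of 4 windows, 0 for both changes of the response (limma; 183 and 147 at an unadjusted p under 0.05), 3 for the control course and 0 for the difference between sets (limma; 268). Without centring they were 28 at 40 to 60 min (20 positive and 8 negative, against 41 and 6), 2 at 120 to 240 min (1 and 1, against 0 and 1), 3 at 480 to 960 min (0 and 3, against 2 and 1) and 13 for the control course (11 and 2, against 1 and 2). With arrays scaled to a common spread they were 0 at 0, 40 to 60 and 120 to 240 min (limma; 134, 204 and 225 at an unadjusted p under 0.05), 77 at 10 to 30 min, 174 at 480 to 960 min, 38 for the mean, 2 for the late change, 0 for the control course (limma; 199) and 1 for the difference between sets. With quantile normalisation they were 1 at 0 min, 80 at 10 to 30 min, 2 at 40 to 60 min, 140 at 480 to 960 min (63 positive and 77 negative, against 2 and 1), 60 for the mean, 1 for the control course and 1 for the difference between sets.

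With the median of the spots 5 were called at 480 to 960 min. Over the 2072 features other than 0 on every array it was 7 there and 15 for the control course, and without the tenth of features that varied most 9 and 11. Without the set term it was 31 at 10 to 30 min, 12 at 40 to 60 min, 84 for the mean, and 0 at 120 to 240 min and for the control course (limma; 141 and 127 at an unadjusted p under 0.05). The Alexa 532 set alone gave 201 at 0 min (5 positive and 196 negative, against 2 and 1), 8 at 10 to 30 min, 0 at 40 to 60 min (limma; 201 at an unadjusted p under 0.05), 1 at 480 to 960 min, 175 for the mean (39 positive and 136 negative, against 136 and 73), 22 for the early and 1 for the late change, and 1 for the control course. The Alexa 546 set alone gave 0 at 0 and at 120 to 240 min (limma; 152 and 208), 70 at 10 to 30 min (34 positive and 36 negative, against 71 and 50) and 62 for the mean, and it has no samples at 480 to 960 min. Fewer samples enter each set.

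With arrays as units and the RNA sample as a random block (correlation −0.202) it was 96 at 40 to 60 min, 8 at 120 to 240 min, 6 at 480 to 960 min, 2 for the late change and 25 for the control course. With Alexa 647 arrays alone it was 6, 282, 103, 5 and 140 over the 5 windows in order of time (the 5 all positive, where the 1 main call was negative), 340 for the mean, 323 for the late change, 7 for the control course and 253 for the difference between sets. With Alexa 532 or 546 arrays alone it was 1 at 10 to 30 min, 1 for the control course, 1 for the difference between sets, and 0 at 0, 40 to 60 and 480 to 960 min and for the mean (limma; 213, 111, 149 and 228 at an unadjusted p under 0.05). With matched times blocked it was 1 at 0 min, 10 at 480 to 960 min and 1 for the early change.

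With a difference of at least 1.5-fold, a stricter threshold, 10 remained at 10 to 30 min and 2 at 40 to 60 min. For the mean 0 remained (limma, where 561 features of any fold had an unadjusted p under 0.05). With the lone array uncorrected it was 0 at 0 min (limma; 124), 23 at 10 to 30 min, 1 at 480 to 960 min, 98 for the mean and 1 for the control course. Without smooth trends it was 186 at 10 to 30 min, 21 at 480 to 960 min, 4 for the late change, 17 for the control course and 2 for the difference between sets. With exact 0 as missing it was 5 at 480 to 960 min (2 positive and 3 negative, against 2 and 1) and 15 for the control course. Without the 7 samples rich in exact 0 it was 26 at 40 to 60 min, 0 at 120 to 240 min (limma; 192), 1 for the control course and 59 for the difference between sets.

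With ratios not turned, which takes each array as culture over reference, it was 0 at 0 min and for the control course (limma; 154 and 337 at an unadjusted p under 0.05), 148 at 10 to 30 min (32 positive and 116 negative), 29 at 40 to 60 min (14 and 15), 15 at 120 to 240 min (0 and 15), 2 at 480 to 960 min (0 and 2), 86 for the mean (7 and 79), 359 for the late change and 75 for the difference between sets. In every comparison 0 of these calls were also main calls on the same side (limma). Of 31 named gene values 27 reversed and 4 kept the side without the call, which were dpsA at 40 to 60 min (0.031), guaB (0.064) and cbiT (−0.047) at 10 to 30 min, and glyA over the mean (−0.039). The reversed values were, at 10 to 30 min dpsA −0.103, gyrA −0.315, gyrB −0.293, psmA −0.035, pyrI 0.075, mdh 0.094, glyA 0.024 and cobN 0.100, and at 40 to 60 min gyrA −0.183, gyrB −0.273, ppsA 0.112 and cobN 0.064. Over the mean they were dpsA −0.126, arcC −0.030, gyrA −0.182, gyrB −0.207, guaB −0.201, uvrB −0.176, htr8 −0.061, sucC 0.246, cobN 0.052, gdhA1 0.129, purL 0.037, cbiT 0.071, mdh 0.068, purD 0.194 and serS 0.166. The results therefore depend on a ratio between fixed channels.

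Of the 60 list tests camera called 2, camera with an estimated correlation 0, fry 17 and its mixed test 0, and camera with ratios not turned 0. In single sets camera called 0 in the Alexa 532 and 1 in the Alexa 546 set.

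Leaving out each RNA sample in turn gave 339 counts, of which 302 were within 1.5 times, and 1054 values of named genes, of which 923 kept their call, 131 lost it and 0 reversed. Counts ranged from 1 to 91 at 0 min, 62 to 139 at 10 to 30 min, 15 to 51 at 40 to 60 min, 0 to 2 at 120 to 240 min, 2 to 38 at 480 to 960 min and 121 to 356 for the mean. They ranged from 0 to 20 for the early change, 0 to 1 for the late change, 1 to 11 for the control course and 0 to 9 for the difference between sets. The samples behind counts that moved by over 1.5 times are named here or in the report. Smaller moves gave 139 at 10 to 30 min without the irradiated sample of 40 min and 51 at 40 to 60 min without that of 30 min, both of the Alexa 532 set, and 2 at 480 to 960 min without any 1 of 9 samples of earlier times, among them the control of 10 min of the Alexa 546 set. At 120 to 240 min 2 were called without the irradiated sample of 240 min of the Alexa 546 set, and the late change had 1 call without its control of 120 min. For the control course 9 were called without the irradiated sample of 10 min of that set, 8 without its irradiated sample of 240 min, its control of 0 min or the irradiated 10 min sample of the Alexa 532 set, and 7, 6 and 5 without the control of 10 min (Alexa 532), the control of 30 min (Alexa 546) and the irradiated sample of 120 min (Alexa 532). For the difference between sets 9 were called without the control of 50 min, 6 without the irradiated sample of 120 min and 5 without that of 10 min, all of the Alexa 546 set, and 1 without either sample of 30 min of the Alexa 532 set. At 480 to 960 min 11 were called without the control of 0 min of either set or the 60 min control of the Alexa 546 set, and 1 each at 0 min without the other 3 samples of that time. Without the single control of 480 to 960 min the comparison in that window could not be made.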

Other observations

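The array-position test in this part was chosen after the result was seen, and the test of neighbouring genes before.

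Beyond the lists, genes of glutamate and phosphoenolpyruvate metabolism gave these values at 10 to 30 min, chosen after they were seen. The glutamate dehydrogenase genes gdhA1, gdhA2 and gdhB were at −0.32 ± 0.11, −0.31 ± 0.10 and −0.22 ± 0.11 (limma adjusted p = 0.0835, 0.0827 and 0.288), none called in that window. With ratios not turned gdhA2 was called on the other side at 0.63 ± 0.11 (limma adjusted p = 0.00384), and gdhA1 was at 0.13 ± 0.10. eno, the enolase gene, was at 0.02 ± 0.08, while ppsA, which acts on the same metabolite, was at −0.30 ± 0.11 (adjusted p = 0.139). The 8 genes called on the negative side at 10 to 30 min had positive values at 480 to 960 min, none of them called (limma adjusted p between 0.42 and 0.71): mdh was at 0.35 ± 0.20, sucD at 0.29 ± 0.17, cobN at 0.26 ± 0.15, pyrI at 0.26 ± 0.20, glyA at 0.26 ± 0.20, purL at 0.22 ± 0.14, cbiT at 0.13 ± 0.16 and serS at 0.11 ± 0.14. Without centring, which moved the median of all features by −0.13 in that window, cbiT and serS turned negative, as both did with arrays scaled to a common spread and serS with quantile normalisation. Most genes of several lists, which hold some of these 8, were positive there, so that side was not particular to the 8. Positive were 14 of 16 genes of nucleotide synthesis, 11 of 12 of the tRNA ligase list and 12 of 14 of amino acid synthesis. All 5 of the tricarboxylic acid cycle were too, against 5 of 11 chemotaxis genes and 1 of 4 phototrophy genes. The window rests on 1 control RNA sample, and 1 of its arrays had 24.6% exact 0. With ratios not turned, mdh (−0.02), cobN (−0.30), pyrI (−0.18), glyA (−0.16), purL (−0.12), serS (−0.21) and sucD were negative in that window, and cbiT (0.10) was positive.

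Unnamed feature 3453 changed by 1.46 ± 0.20 in the controls from 0 min to 120 to 240 min and differed by −1.01 ± 0.17 between the arms at 120 to 240 min, and at 10 to 30 min it differed by −0.18 ± 0.13. Both called values rest on the same 3 control samples. With ratios not turned they were 0.09 ± 0.18 and −0.15 ± 0.15, neither called.

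A hypothesis was that genes next to each other on the chromosome move together over the samples beyond the groups. Over 28 pairs of named genes at most 2 genes apart, holding 42 genes, the mean correlation of residuals was 0.355, against a mean of 0.0854 and a highest value of 0.310 over 9999 shuffles of gene positions (permutation p = 1e-04, the smallest they can give). Of the pairs 64.3% had the same side over the mean of 4 windows, against 49.9% for shuffled positions (permutation p = 0.0959). Features printed next to each other on the array also correlated, at 0.281 against 0.0153 over all pairs of features. The 8 neighbouring pairs more than 100 features apart on the array had a mean of 0.117, against 0.0865 for shuffled positions (permutation p = 0.404), and the 20 closer pairs 0.450. With 8 distant pairs, a shared position on the array and on the chromosome cannot be told apart as the source. The order of genes was taken from the assembly of another strain.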
